A study of Mus musculus with 18 samples.

How the data were processed

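The study sorted LT-HSC, MPP3 and MPP4 from the bone marrow of 3 WT and 3 Helios KO mice, and poly(A) RNA was sequenced. Per the labels' protocols, total RNA came from 10000 to 40000 cells per extraction (RNeasy Plus Micro), cDNA was made from 1000 pg of RNA with SMART-Seq v4, and libraries were made from 600 pg of cDNA with Nextera XT, with 12 cycles of amplification in each of the 2 steps. The reads carry no molecular identifiers, so the floors given for 0 reads cover counting error only. The submitters' processing notes name bcl2fastq 2.17.1.14, DESeq without a version, and the genome build mm10. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical gene copies may therefore have been split between genes in ways the counts do not show, and such genes are uncertain.

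The authors deposited whole-number read counts per Ensembl gene, per the file headers raw, for 29437 genes in all 18 libraries; these counts were the input to every test. The authors also deposited a normalized signal per library, per the file headers, which equals the count divided by one size factor per library (0.8118 to 1.7233), and the same signal divided by the median transcript length in kb. The median transcript length in bases is a column of the authors' deposited table. The authors deposited log2 fold changes of KO against WT and p-values with adjusted p-values for the 3 populations, per the file headers; the model behind them is not given in the sources used here. Every column of per-sample values was matched to a sample by its title. Gene symbols and coordinates were those of the deposited table; 29428 gene IDs were found in GENCODE M21, and 28716 of the genes (97.6%) had the same coordinates there. A further 23 IDs shared a symbol with another ID. Total counts were 21053050 to 45410959 per library, no entry lacked a gene, and 0 pairs of libraries had identical counts.

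Genes were kept with edgeR's filterByExpr over the 6 groups (16325 genes) and scaled by TMM. The quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) was fitted to all 18 libraries with 1 mean per group, since 3 libraries per group leave few degrees of freedom to estimate the spread (common dispersion 0.164, prior degrees of freedom 4.32). Contrasts were KO against WT in each population, the differences of these effects between populations, and the populations against each other in WT. Benjamini-Hochberg adjustment was applied within each contrast at 0.05, and standard errors were taken as the log2 fold change over the square root of F. DESeq2 1.42.0 and limma 3.58.1 voom, with the mouse as a random block, were run beside it. A gene with 0 reads in all 3 libraries of a group was given a bound from a floor of 3 reads over the group. Where a median is given with the floor, members with 0 reads in a group and at most 3 in the other were left out.

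Gene lists, named genes and alternatives were fixed before the data were examined, apart from those described as added later. The lists were megakaryocyte and platelet genes, lymphoid priming genes, erythroid genes, granulocyte and monocyte genes, stem cell identity, genes rising in stem cells with age, cell cycle, interferon response, immediate early and stress genes, NF-kB targets, Notch targets, the Ikaros family, the genes of the sorting gates, ribosomal proteins, mitochondrial transcripts, sex-linked genes, and markers of mature B and plasma cells, T and NK cells, mature neutrophils, macrophages and dendritic cells, mast cells with basophils and eosinophils, and stroma with endothelium. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists and the 3 populations, and separately over the 3 differences between populations. Camera with an estimated correlation and fry were run beside it, and no list passed under either in KO against WT, by fry's test of direction. The summed CPM of a list was compared between genotypes with an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

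Genes were named by a fixed rule. Ikzf2 was always named. In KO against WT up to 10 higher and 10 lower genes were named, those with the largest change among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and all 3 KO libraries on one side of all 3 WT libraries, without predicted or clone-named genes. Of each list up to 4 members past the threshold were named, or otherwise up to 2 with the smallest p, and of the differences between populations up to 5 genes past the threshold. In the WT populations the gate genes and up to 2 members of each of 5 lists (megakaryocyte and platelet, lymphoid priming, granulocyte and monocyte, stem cell identity, cell cycle) were named. Genes outside the rule, Itgax and Nlrp6 among them, are said in the text to have been named after their values were seen, as were the genes near Ikzf2 and the members named as passing adjusted over a list alone or in the authors' deposited table. Some genes that the rule or the counts would name are not reported here.

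The numbers in the sample titles were taken to mark mice, so that libraries of a genotype with the same number came from the same mouse. Across populations, deviations from the group means of such libraries correlated at r = 0.065 to 0.291, with 16 of 18 pairs over 0.1, and the mouse was used as a block in an alternative for the comparisons between populations. A WT and a KO library of the same number come from different mice, and their pairing is treated as an alternative only. Further alternatives were DESeq2's size factors, no filter on low counts, only the libraries of 1 population, a minimum log2 fold change of 1, windows of 5 and 50 Mb around Ikzf2, and leaving out each library or mouse in turn. Robust estimation, a term for the libraries numbered 1, the libraries numbered 2 and 3 alone, leaving out libraries with neutrophil or plasma cell transcripts, leaving out immunoglobulin genes, the calls of DESeq2 and of the authors' deposited table near Ikzf2, and Gene Ontology terms from the deposited table were added after seeing the data. Transcripts were aligned to Rplp0 with blastn 2.17.0. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

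The tests were tested on simulated data drawn from the real means and library sizes with 200 genes changed in each population. The changed genes had a mean of at least 5 CPM. Counts were drawn independently, without differences shared by the genes of a library or by the libraries of a mouse. In the LT-HSC, MPP3 and MPP4 comparisons 178, 172 and 169 genes passed by edgeR, against 10, 1 and 2 in the real data. With so many genes passing, the adjustment asks less of each gene than in the real data. For both reasons the shares recovered may exceed those in the real data. Of genes changed by a log2 fold change of 1, edgeR recovered 73% in the LT-HSC comparison and 65% in each of MPP3 and MPP4, and of those changed by 2 it recovered 92%, 91% and 95%, over 15596 genes; 7.3%, 7% and 5.3% of its calls were genes that had not been changed. DESeq2 recovered 77%, 78% and 76% and 94%, 97% and 98% over 16325 genes, with 26.3%, 21.6% and 20.2% of its calls on genes that had not been changed. A simulated list of 40 genes shifted by 0.5 gave a camera p of 6.86e-18, and an unshifted list 0.268. These simulated genes did not vary together. In LT-HSC the estimated correlation was 0.189 for the real megakaryocyte and platelet list and 0.636 for cell cycle. The simulation therefore cannot show whether camera at the preset correlation holds its error rate on the real lists. Splits of the real libraries other than by genotype, given below, also reached a camera p under 0.05. They did so in each population for the megakaryocyte and platelet list and for the lymphoid priming list.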

Results

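Gene-level read counts from poly(A) RNA were analysed for 18 libraries made from the bone marrow of mice aged 10 weeks. The mice were wild type (WT) or knocked out (KO) for Helios, a zinc finger transcription factor of the Ikaros family that is encoded by Ikzf2, with 3 mice per genotype. From each mouse 3 populations of cells negative for lineage markers and positive for Sca1 and Kit were sorted, which gave 6 groups of 3 libraries. Long-term hematopoietic stem cells (LT-HSC) were sorted as negative for CD48 and positive for CD150. The multipotent progenitors MPP3 and MPP4 were both positive for CD48 and negative for CD150. MPP3, which are biased towards the myeloid lineages, were Flt3-negative, and MPP4, biased towards the lymphoid lineages, were Flt3-positive. The series asks how the loss of Helios shifts the balance of megakaryocyte and lymphoid gene expression in these cells.

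Total counts per library ran from 23049108 to 45410959 in LT-HSC WT and from 21053050 to 28153044 in LT-HSC KO. They ran from 23995247 to 27711201 in MPP3 WT and from 26107781 to 29613609 in MPP3 KO, and from 27475503 to 30894937 in MPP4 WT and from 21858683 to 28091202 in MPP4 KO. Between 17362 and 20272 genes per library had at least 1 read. The libraries numbered 1 had fewer of them (17362 to 18896) than those numbered 2 (19185 to 19757) or 3 (19700 to 20272), and each group held 1 library of each number. The first principal component carried 49.8% of the variance and separated the populations. Levels are CPM after TMM scaling, as mean ± SD of 3 libraries (n = 3), and log2 fold changes are given ± their standard error.

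Ikzf2, on chromosome 1 from 69531214 to 69687245 (mm10, ENSMUSG00000025997), was lower in every KO library than in every WT library of its population. In LT-HSC it stood at 39.83, 42.02 and 39.35 CPM in the WT libraries and at 11.13, 6.56 and 11.17 CPM in the KO libraries. In MPP3 the WT libraries had 42.58, 65.56 and 38.29 CPM and the KO libraries 19.03, 19.03 and 23.95 CPM. In MPP4 the WT libraries had 37.13, 34.05 and 27.07 CPM and the KO libraries 3.55, 11.14 and 10.21 CPM. The log2 fold change of Ikzf2 was -2.07 ± 0.33 in LT-HSC, where it passed the test (edgeR adjusted p = 0.0259). It was -1.24 ± 0.32 in MPP3 (edgeR adjusted p = 0.66) and -1.98 ± 0.33 in MPP4 (edgeR adjusted p = 0.0656). By DESeq2, and in the authors' deposited table, Ikzf2 passed in all 3 populations. The difference in the KO effect on Ikzf2 was 0.83 ± 0.45 between MPP3 and LT-HSC, 0.09 ± 0.46 between MPP4 and LT-HSC and -0.74 ± 0.45 between MPP4 and MPP3 (edgeR adjusted p = 1 for each). Reads on Ikzf2 remained in all KO libraries, and which exons the KO allele lacks is not given in the sources used here. In WT cells Ikzf2 did not pass between populations. Its log2 differences were 0.27 for MPP3 against LT-HSC, -0.30 for MPP4 against LT-HSC and -0.58 for MPP4 against MPP3 (edgeR adjusted p = 0.615, 0.527 and 0.47).

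**Figure D1:**
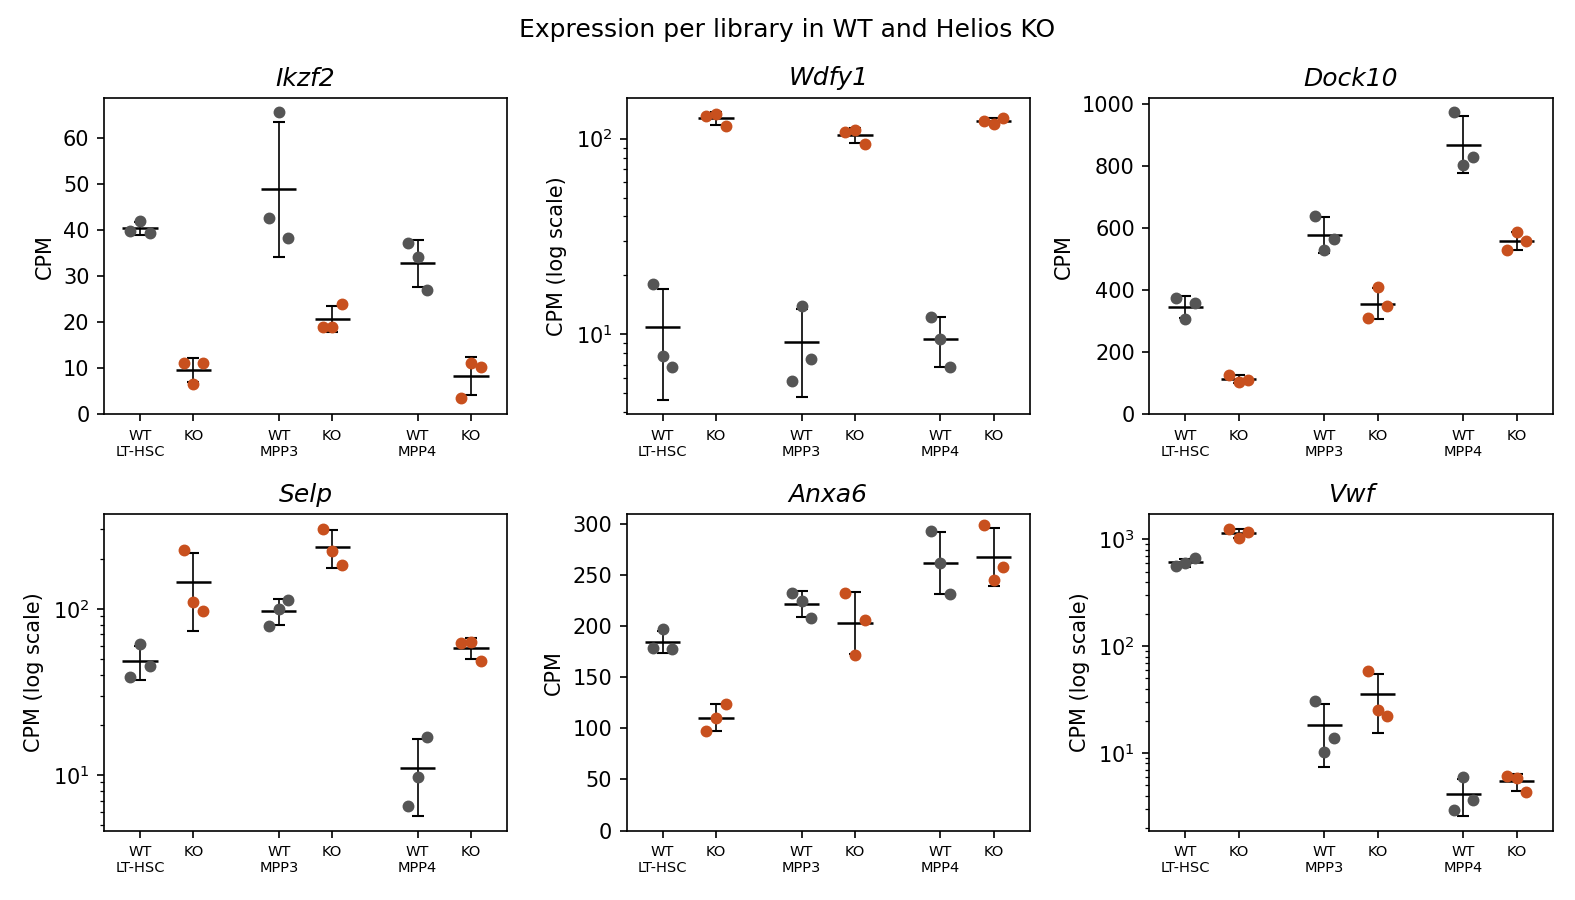
CPM after TMM scaling of Ikzf2, Wdfy1, Dock10, Selp, Anxa6 and Vwf in each library by population and genotype (points, libraries; line, mean; bar, SD of 3; log axis for Wdfy1, Selp and Vwf). Ikzf2 lies lower in each KO library than in the WT libraries of its population, and Wdfy1 means are 127, 105 and 123 CPM in KO against 10.9, 9.08 and 9.48 CPM in WT in LT-HSC, MPP3 and MPP4.

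The WT libraries showed the genes of the sorting gates. Cd48 rose from 6.05 ± 3.81 CPM in LT-HSC to 313 ± 10.3 CPM in MPP3 and 285 ± 5.95 CPM in MPP4, and Slamf1, which encodes CD150, fell from 69.7 ± 5.32 CPM in LT-HSC to 5.66 CPM in MPP3 and 0.87 CPM in MPP4. Flt3, a cytokine receptor of lymphoid-biased progenitors, rose from 90.2 ± 24 CPM in LT-HSC to 786 ± 88.9 CPM in MPP3 and 3280 ± 442 CPM in MPP4. Vwf, the platelet adhesion protein von Willebrand factor, was higher in LT-HSC, with a log2 fold change of -5.06 ± 0.42 in MPP3 and -7.18 ± 0.47 in MPP4 (edgeR adjusted p = 7.43e-07 and 1.86e-08). Tespa1, which acts in thymocyte signalling, was higher in MPP3 and MPP4 than in LT-HSC by log2 6.23 and 6.51. Satb1, a chromatin organiser of lymphoid cells, was higher in MPP4 by 5.56 ± 0.32 (edgeR adjusted p = 4.26e-09). Tek, the angiopoietin receptor of quiescent stem cells, stood at a log2 fold change of -5.89 ± 0.3 in MPP4 against LT-HSC (edgeR adjusted p = 1.07e-09). Mllt3, a regulator of stem cell maintenance, stood at -3.14 in MPP3 and -3.64 in MPP4. The cell cycle gene Mcm7, part of the replicative helicase, was higher in MPP3 by 0.85 ± 0.17 (edgeR adjusted p = 0.00271) and in MPP4 by 0.83. Between the progenitors, MPP4 exceeded MPP3 in Flt3 by 2.06 ± 0.19 and in Notch1 by 2.10 ± 0.21 (edgeR adjusted p = 6.49e-06 and 1.51e-05). Itga2b, the platelet integrin CD41, stood at -4.48 ± 0.39 (edgeR adjusted p = 4.51e-06). The granule gene Nkg7 was higher in MPP3 than in LT-HSC by 3.30 (edgeR adjusted p = 3.52e-10).

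By edgeR's quasi-likelihood test over 16325 genes, 2831 genes passed between MPP3 and LT-HSC in WT cells (1580 higher and 1251 lower in MPP3). Between MPP4 and LT-HSC 4435 passed (2304 higher, 2131 lower), and between MPP4 and MPP3 786 (358 higher, 428 lower). A log2 fold change of at least 1 was reached by 1201, 2174 and 482 of them. DESeq2 gave 3693, 5218 and 1230 genes and limma voom 4157, 5798 and 1163. Leaving out a mouse lowered the MPP3 and LT-HSC count to 1461 (WT 1), 1405 (WT 2) or 1296 (WT 3). It lowered the MPP4 and LT-HSC count to 2613 (WT 2) or 2919 (WT 3), and the count between MPP4 and MPP3 to 366 (WT 1), 382 (WT 2) or 480 (WT 3).

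In LT-HSC the comparison of KO with WT gave 3 higher and 7 lower genes. Wdfy1, an endosomal adaptor of Toll-like receptor signalling on chromosome 1 from 79702262 to 79776143 (mm10), rose to 127 ± 9.43 CPM from 10.9 ± 6.25 CPM in WT, 11.7-fold (log2 3.55 ± 0.35, edgeR adjusted p = 0.000166). Dock10, an exchange factor for small GTPases on chromosome 1 from 80501073 to 80758527, fell to 113 ± 12.4 CPM from 347 ± 35.6 CPM (log2 -1.62 ± 0.12, edgeR adjusted p = 6.21e-06). Arl11, a small GTPase of the ARF-like family, was lower in KO at 2.04 ± 0.626 against 6.66 ± 2.9 CPM (edgeR adjusted p = 0.0221). So were Ncf4, a subunit of the phagocyte NADPH oxidase, at 5.21 ± 0.798 against 11.1 ± 1.54 CPM, and Anxa6, a membrane-binding annexin, at 111 ± 13.2 against 185 ± 10.8 CPM (edgeR adjusted p = 0.0229 and 0.0402). Tuba1c, an alpha tubulin, was higher at 33 ± 1.39 against 20.7 ± 1.05 CPM (edgeR adjusted p = 0.041). In each of these genes the 3 KO libraries lay on one side of the 3 WT libraries.

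A pair of weakly expressed genes, named here after their values were seen, also passed. Itgax, the dendritic cell integrin CD11c, had 0 reads in the 3 KO libraries and 92 reads in the WT libraries, at least 24.9-fold lower (edgeR adjusted p = 0.0221). Nlrp6, an inflammasome sensor, had 77 reads in KO and 0 in WT, at least 31.7-fold higher (edgeR adjusted p = 0.041). These folds were set against a floor of 3 reads over the 3 libraries of a group.

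At an unadjusted p under 0.05 LT-HSC had 1832 genes, DESeq2 gave 111 higher and 130 lower genes including all 10, and limma voom 25 and 8. Of the 10 genes, 5 passed by limma voom (Wdfy1, Tuba1c, Anxa6, Ikzf2 and Dock10). In the edgeR fit to the 6 LT-HSC libraries alone 3 of the 10 passed (Wdfy1, Ikzf2 and Dock10). With the libraries numbered 2 and 3 alone edgeR gave 7 higher and 12 lower, and with no filter on low counts it gave 12 lower. Without WT 1 the counts were 5 higher and 9 lower. Without KO 1, WT 2, KO 2, WT 3 or KO 3 there was 1 higher, and 2, 3, 1, 2 and 2 lower in that order, with Wdfy1 and Dock10 passing in each case. Tuba1c, Nlrp6 and Anxa6 did not pass in any fit with 1 library left out (edgeR adjusted p from 0.0633 to 0.203). Ikzf2 passed without WT 1 (edgeR adjusted p = 0.0473) and not without KO 1, WT 2, KO 2, WT 3 or KO 3 (0.131, 0.0835, 0.125, 0.0532 and 0.0996). Arl11 did not pass without KO 1, WT 2, KO 2 or KO 3 (edgeR adjusted p = 0.131, 0.0543, 0.0544 and 0.0996). Itgax did not pass without KO 1, KO 2, WT 3 or KO 3 (edgeR adjusted p = 0.131, 0.0883, 0.0532 and 0.0967), and Ncf4 not without WT 1, KO 1, KO 2, WT 3 or KO 3 (0.0552, 0.105, 0.114, 0.0683 and 0.0967).

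The megakaryocyte and platelet genes were higher as a group in LT-HSC KO, with 31 of 41 tested members above 0 and 10 below. Their median log2 fold change was 0.25 (camera adjusted p = 0.00391, and adjusted p = 0.805 with an estimated correlation). The list summed to 10100, 8580 and 9370 CPM in the WT libraries and to 12000, 10500 and 9950 CPM in the KO libraries. KO 3 thus lay within the WT range (exact two-sided permutation p = 0.2). Selp, the platelet adhesion receptor P-selectin, stood at 145 ± 71.4 CPM in KO and 48.4 ± 11.3 CPM in WT (log2 1.58 ± 0.33, edgeR adjusted p = 0.131). Vwf had 1247.15, 1026.36 and 1173.43 CPM in the KO libraries and 561.67, 597.02 and 666.58 CPM in the WT libraries (log2 0.92 ± 0.35, edgeR adjusted p = 0.356). Lat, an adaptor of platelet and T cell receptor signalling, stood at log2 0.59 ± 0.17 (edgeR adjusted p = 0.254). No member passed over all genes by edgeR, 1 passed adjusted over the list alone (Selp), and Selp and Lat passed in the authors' deposited table. Vwf passed as higher in the edgeR fit to the 6 LT-HSC libraries alone and by limma voom, and not by DESeq2. The list did not pass without KO 1 (camera adjusted p = 0.15), without WT 2 (0.103), or without both WT 2 and WT 3, which carried neutrophil transcripts and whose removal leaves 1 WT library (0.465). Its adjusted p ranged from 0.000606 to 0.805 by camera or fry across all alternatives.

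The lymphoid priming genes were lower as a group in LT-HSC KO, with 24 of 42 tested members below 0 and 17 above. Their median was -0.13, or -0.20 with 1 member at 0 reads in a group set to its bound and 2 members at or under the floor in both groups left out (camera adjusted p = 0.0224, and adjusted p = 0.734 with an estimated correlation). The list summed to 3670, 3900 and 3840 CPM in the WT libraries and to 3430, 3470 and 3220 CPM in the KO libraries (exact two-sided permutation p = 0.1, the smallest possible). By edgeR 1 member passed over all genes and 2 passed adjusted over the list alone, among them Ccr7, a chemokine receptor of lymphocytes named after its values were seen. With any 1 library left out the median shrank to between -0.09 and -0.022. The camera call was absent without KO 1 (adjusted p = 0.051), WT 2 (0.242), WT 3 (0.102), KO 3 (0.101), or both WT 2 and WT 3, where the median against the 1 WT library left was 0.05 (0.668). Its adjusted p ranged from 0.00806 to 0.734 by camera or fry across all alternatives.

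Genes that rise in stem cells with age were also higher as a group in LT-HSC KO (24 of 35 above 0, median log2 0.35, camera adjusted p = 0.00777, adjusted p = 0.364 with an estimated correlation). Clu, the extracellular chaperone clusterin, stood at 121 ± 19.6 CPM against 44.9 ± 13.2 CPM (log2 1.43 ± 0.31, edgeR adjusted p = 0.138). Clu and Selp were the 2 members past the threshold adjusted over the list alone, against 0 over all genes. Ribosomal protein genes were higher in small steps, with 75 of 84 above 0 and a median of 0.28 (camera adjusted p = 3.82e-05, adjusted p = 0.899 with an estimated correlation). By edgeR 0 of them passed over all genes or adjusted over the list alone. The list summed to 4820, 5780 and 5930 CPM in the WT libraries and to 5550, 5800 and 7630 CPM in the KO libraries. KO 1 and KO 2 thus lay within the WT range (exact two-sided permutation p = 0.5). The Ikaros family list (5 members, Ikzf2 among them) had all 5 below 0 (median -0.55, camera adjusted p = 0.00414, adjusted p = 0.167 with an estimated correlation). Of these 1, Ikzf2, passed over all genes and adjusted over the list alone. The call is partly fixed by the design, because the list holds the deleted gene, and without Ikzf2 its 4 members are too few for the test. The cell cycle list did not pass (30 of 40 above 0, median 0.18, camera adjusted p = 0.142). Its 1 member Kif23, a kinesin of cytokinesis, was lower adjusted over the list alone (log2 -0.74 ± 0.18).

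Mature neutrophil transcripts were lower in LT-HSC KO as a group, with all 14 tested members below 0. The median was -4.62, or -4.33 with members at 0 reads set to their bound (camera adjusted p = 4.16e-06, adjusted p = 0.45 with an estimated correlation). S100a9, a calcium-binding protein abundant in neutrophils, stood at 0.689 CPM in KO against 12.5 ± 16.2 CPM in WT (log2 -4.16 ± 1.15, edgeR adjusted p = 0.233), so that its SD in WT exceeded its mean. No member passed over all genes by edgeR, 8 passed adjusted over the list alone, and Mmp9, S100a8 and S100a9 were lower in the authors' deposited table. The summed level of the list was 3.86, 82.1 and 253 CPM in the LT-HSC WT libraries 1, 2 and 3 and 3.64, 9.21 and 5.17 CPM in the KO libraries (exact two-sided permutation p = 0.3, the smallest possible being 0.1).

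**Figure D2:**
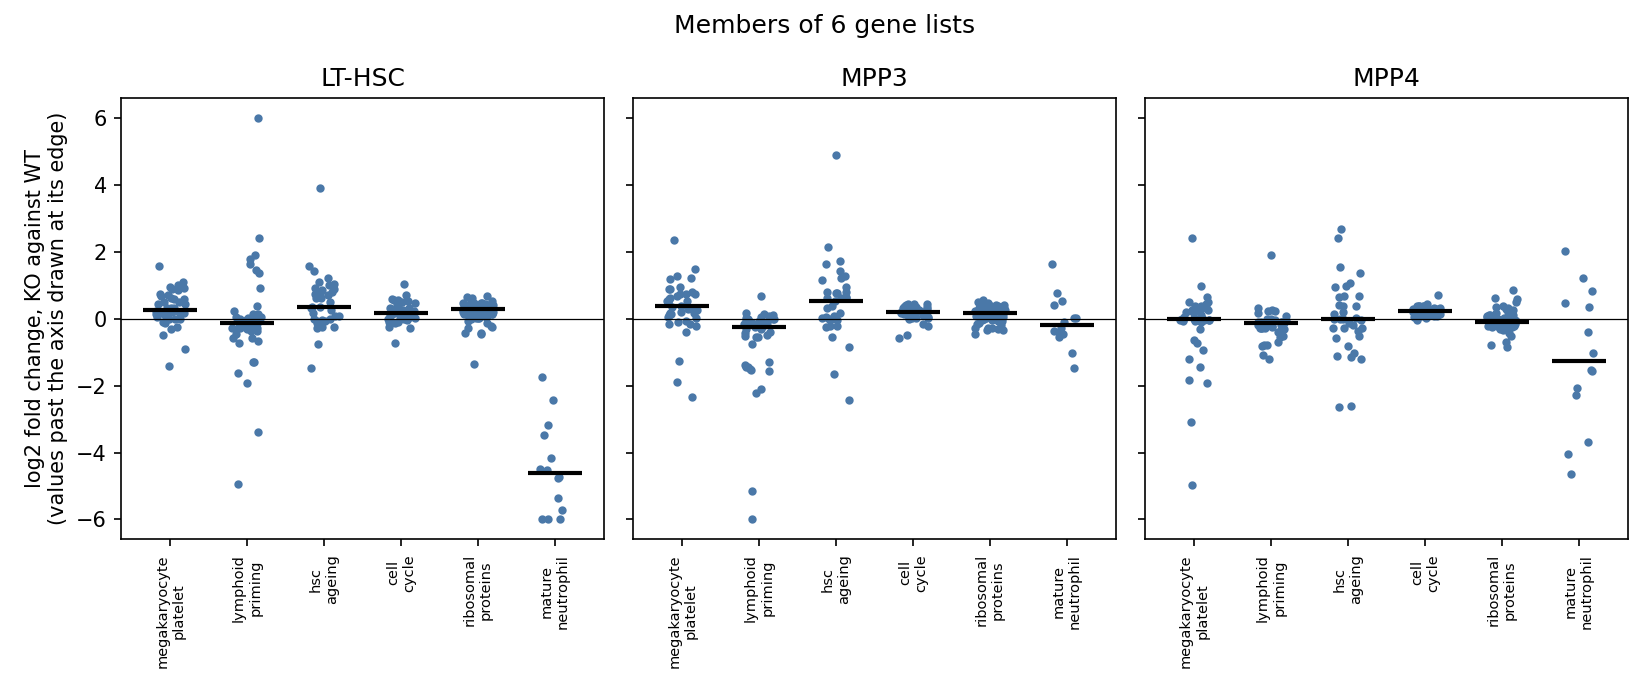
Log2 fold change of KO against WT for the tested members of 6 gene lists in each population (points, genes, drawn at the limit beyond 6; line, median). The megakaryocyte and platelet medians are 0.25, 0.38 and 0 and the lymphoid priming medians -0.13, -0.24 and -0.12 in LT-HSC, MPP3 and MPP4.

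In MPP3 a single gene passed: Wdfy1 rose to 105 ± 9.27 CPM from 9.08 ± 4.32 CPM in WT (log2 3.53 ± 0.35, edgeR adjusted p = 0.000392). Dock10 stood at -0.70 ± 0.12 (edgeR adjusted p = 0.192) and passed by DESeq2 and by limma voom. Selp had 236 ± 60.9 CPM in KO and 97.3 ± 17.2 CPM in WT (log2 1.28 ± 0.33, edgeR adjusted p = 0.66), and Sdc1, the plasma cell surface proteoglycan CD138, stood at -1.22 ± 0.27 (edgeR adjusted p = 0.495). By edgeR 1 gene was higher and 0 lower, against 750 genes at an unadjusted p under 0.05, 20 higher and 25 lower by DESeq2 and 1 and 1 by limma voom. Chance alone would on average give a share of 0.05 of the 16325 tested genes. The 750 genes lay below this share, and the 1832 of LT-HSC above it. With the libraries numbered 2 and 3 alone edgeR gave 4 higher (Wdfy1, Gm8730, Gm9625 and AC123956.1) and 0 lower. A single lower gene appeared without KO 1 (Sdc1), KO 2 (Clock) or WT 3 (Igkv1-117) and with no filter on low counts (Igkv1-117). Without the 3 libraries carrying plasma cell transcripts (WT 1, WT 2 and KO 1) 1 WT library was left against 2 KO libraries, and the counts were 0 higher and 1 lower (Sdc1). Wdfy1 then stood at log2 3.77 (edgeR adjusted p = 0.0593), so that its call and not its fold was lost. All of these but Wdfy1 and Sdc1 are named after their values were seen, and Gm8730 and Gm9625, copies of the ribosomal gene Rplp0, were high in KO mice 2 and 3 and not in KO mouse 1.

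The megakaryocyte and platelet list was higher in MPP3 KO (32 of 41 members above 0 and 9 below, median log2 0.38, camera adjusted p = 3.82e-05, adjusted p = 0.65 with an estimated correlation). The median was 0.211 without WT 3 (camera adjusted p = 0.0292) and up to 0.539 with another library left out, and a split of the 6 libraries other than by genotype gave a camera p of 9.44e-13 against 3.03e-06. The list summed to 4870, 4640 and 3950 CPM in the WT libraries and to 5140, 5330 and 4610 CPM in the KO libraries. KO 3 thus lay within the WT range (exact two-sided permutation p = 0.3). Beside Selp, Cd9, a tetraspanin of platelets and their precursors, stood at 0.61 ± 0.19 (edgeR adjusted p = 0.895). The lymphoid priming list was lower, with 35 of 42 members below 0 and 7 above (median -0.24, camera adjusted p = 5.72e-06, adjusted p = 0.167 with an estimated correlation). It summed to 7970, 8530 and 6090 CPM in the WT libraries and to 6780, 5110 and 4950 CPM in the KO libraries. KO 1 thus lay within the WT range (exact two-sided permutation p = 0.2). Il7r, the interleukin 7 receptor of lymphoid progenitors, had 1.78 CPM in KO against 7.65 CPM in WT (log2 -2.10 ± 0.89, edgeR adjusted p = 1). Rag1, which cuts antigen receptor genes, had 0 against 32 reads, at least 11.4-fold lower (edgeR adjusted p = 0.66). The Rag1 reads came from WT 1 and WT 2 (14 and 18), and WT 3 had 0 reads, as in KO. By edgeR 0 members of either list passed over all genes or adjusted over the list alone, and Selp alone of the megakaryocyte list passed in the authors' deposited table. Immunoglobulin transcripts of plasma cells were high in WT 1, WT 2 and KO 1, although the cells were sorted as lineage-negative, Sca1-positive and Kit-positive. Without these libraries, which leaves 1 WT library, the lymphoid priming median was -0.10 (camera adjusted p = 0.116). With so few libraries this does not show whether plasma cell RNA accounts for the list. Without the immunoglobulin genes of the list the median was -0.22 (camera adjusted p = 3.59e-06). The adjusted p ranged from 1.18e-06 to 0.167 by camera or fry across all alternatives.

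Genes that rise in stem cells with age were higher in MPP3 KO as well (24 of 35 above 0 and 9 below, median log2 0.54, camera adjusted p = 1.18e-06, adjusted p = 0.0782 with an estimated correlation). With 2 members at or under the floor of 3 reads in both groups left out the median was 0.61. Aldh1a1, a retinaldehyde dehydrogenase of stem cells, stood at 20 against 6.1 CPM (edgeR adjusted p = 0.494) and Clu at log2 2.14 ± 0.45 (edgeR adjusted p = 0.495). Over all genes 0 members passed by edgeR, and 5 passed adjusted over the list alone: Clu, Selp, Sult1a1, Neo1 and Aldh1a1. Of these, Clu had 60, 26 and 39 reads in the KO libraries and 4, 12 and 10 in the WT libraries. Neo1 had 59, 0 and 18 reads in KO and 1, 0 and 1 in WT. The cell cycle list was higher in small steps (36 of 40 above 0, median 0.22, camera adjusted p = 0.00523, adjusted p = 0.901 with an estimated correlation), although its summed level in KO 2, 6470 CPM, lay below the 6700 to 7620 CPM of the WT libraries. So was the ribosomal protein list (67 of 84 above 0, median 0.18, camera adjusted p = 4.06e-05, adjusted p = 0.899 with an estimated correlation). Without the libraries with plasma cell transcripts, again with 1 WT library, the cell cycle median was 0.02 and the ribosomal protein median -0.09.

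In MPP4 both genes that passed were higher in KO. Wdfy1 rose to 123 ± 4.1 CPM from 9.48 ± 2.7 CPM (log2 3.70 ± 0.36, edgeR adjusted p = 0.00021). Selp, on chromosome 1 from 164115264 to 164150026 (mm10), rose to 58.1 ± 8.3 CPM from 11 ± 5.38 CPM (log2 2.40 ± 0.35, edgeR adjusted p = 0.031). Ghr, the growth hormone receptor, stood higher without passing at log2 2.69 ± 0.46 (edgeR adjusted p = 0.0659). Epor, the erythropoietin receptor, had 17, 3 and 38 reads in the KO libraries and 1, 0 and 0 in the WT libraries (edgeR adjusted p = 0.0656), under the floor in WT. Dock10 stood at -0.64 ± 0.12 (edgeR adjusted p = 0.119), and Sdc1 at 70.3 ± 5.59 against 147 ± 27.1 CPM (log2 -1.06 ± 0.26, edgeR adjusted p = 0.607). By edgeR 2 genes were higher and 0 lower, against 653 at an unadjusted p under 0.05, 25 higher and 14 lower by DESeq2 and 1 and 2 by limma voom. The 653 genes lay below a share of 0.05 of the 16325 tested genes. With the libraries numbered 2 and 3 alone edgeR gave 7 and 0. Without WT 1, KO 1 or KO 3 there were 3 higher genes, without WT 2 there was 1 and without WT 3 there were 5. With no filter on low counts there were 6 higher and 1 lower (Ikzf2). Selp did not pass without WT 1, KO 1, WT 2 or KO 2 (edgeR adjusted p = 0.141, 0.0551, 0.203 and 0.0997). Nor did it pass with the replicate number as a block (0.0759), in the fit to the 6 MPP4 libraries alone (0.301) or by limma voom (adjusted p = 0.11).

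The megakaryocyte and platelet list did not pass in MPP4, where 20 members were above 0 and 20 below (camera adjusted p = 0.326). The median was 0 (0.017 with 1 member at 0 reads in a group set to its bound and 2 at or under the floor left out) and the mean -0.22, while the test pointed upwards. Selp was its 1 member past the threshold, over all genes and adjusted over the list alone. The list passed, with the test pointing upwards, without KO 1 (camera adjusted p = 0.000894), without WT 2 (0.0049) and with the libraries numbered 2 and 3 alone (0.0391). Its adjusted p ranged from 0.000894 to 0.986 by camera or fry across all alternatives. The list summed to 2860, 3030 and 2620 CPM in the WT libraries and to 2510, 3390 and 3080 CPM in the KO libraries (exact two-sided permutation p = 0.7). The lymphoid priming list was lower in MPP4 KO (35 of 42 members below 0 and 7 above, median -0.12, camera adjusted p = 0.0422, adjusted p = 0.744 with an estimated correlation). It had 0 members past the threshold by edgeR over all genes or adjusted over the list alone. It summed to 13900, 12300 and 11100 CPM in the WT libraries and to 13600, 10400 and 9500 CPM in the KO libraries (exact two-sided permutation p = 0.4). Rag2, the partner of Rag1, had 22.9 CPM in KO against 48.6 CPM in WT (log2 -1.08 ± 0.61, edgeR adjusted p = 1). The lymphoid list did not pass without WT 1, where its median was 0.010 (camera adjusted p = 0.943), or without WT 2, KO 2 or KO 3 (0.0538, 0.13 and 0.551). With the libraries numbered 2 and 3 alone it had a camera adjusted p of 0.317 and with no filter on low counts 0.082, in a range of 0.00348 to 0.943.

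Cell cycle genes were higher in MPP4 KO in small steps, with 39 of 40 members above 0 (median log2 0.24, camera adjusted p = 0.000203, adjusted p = 0.901 with an estimated correlation). The libraries disagreed: the list summed to 10100, 6150 and 8700 CPM in KO 1, KO 2 and KO 3 and to 7040, 6960 and 7980 CPM in WT, so that KO 2 lay below every WT library (exact two-sided permutation p = 0.6). Ribosomal protein genes were lower, with 60 of 84 below 0 (median -0.11, camera adjusted p = 0.0416, adjusted p = 0.901 with an estimated correlation). Genes that rise in stem cells with age did not pass in MPP4 (median 0, or 0.08 with 5 members at or under the floor left out, camera adjusted p = 0.142). Selp passed over all genes, and 2 members, Selp and Ghr, adjusted over the list alone. The Ikaros family list, which holds Ikzf2 itself, had a camera call in the lower direction with 2 members above 0 (3 of 5 below 0, median -0.04, or -1.01 with 1 member at or under the floor left out, camera adjusted p = 0.00425, adjusted p = 0.167 with an estimated correlation). Of its members 2 passed adjusted over the list alone, Ikzf2 and Ikzf4, a related family member at log2 -4.09 ± 1.18 (edgeR adjusted p = 0.966). The Ikzf4 value rests largely on WT 1 (4.73, 0.43 and 0.55 CPM in the WT libraries) and ran from -4.795 to -2.139 across the alternatives. In MPP3 the Ikaros family list had a median of 0.11 and a mean of -0.17 with a test pointing downwards (camera adjusted p = 0.403). Ikzf2 was its 1 member adjusted over the list alone.

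Whether the KO effect differed between populations was tested directly. The number of genes that passed was 0 for MPP3 against LT-HSC, 0 for MPP4 against LT-HSC and 0 for MPP4 against MPP3 by edgeR. Beside these stood 602, 1086 and 527 genes at an unadjusted p under 0.05, 4, 49 and 8 by DESeq2 and 0, 0 and 0 by limma voom with the mouse as a random block. The 602 and 527 genes lay below a share of 0.05 of the 16325 tested genes, and the 1086 above it. The difference for Dock10 between MPP3 and LT-HSC was 0.92 (edgeR adjusted p = 0.388). In edgeR with the mouse as a fixed block 1 gene passed between MPP4 and LT-HSC and 0 in the other comparisons. DESeq2's 4 genes between MPP3 and LT-HSC were Dock10, Arl11, Gpr141 and Nlrp6. These and the genes of this paragraph were named after their values were seen. Without the WT mouse 3 edgeR gave 2 genes between MPP4 and LT-HSC and the same 2 between MPP4 and MPP3 (D630039A03Rik and Shroom4), and without the WT mouse 1 it gave 1 between MPP4 and MPP3. The difference in the megakaryocyte and platelet list had a camera adjusted p of 0.871 for MPP3 against LT-HSC, 0.285 for MPP4 against LT-HSC and 0.133 for MPP4 against MPP3. For the lymphoid priming list the camera adjusted p was 0.65, 0.65 and 0.141. The mature neutrophil list differed between MPP3 and LT-HSC and between MPP4 and LT-HSC (camera adjusted p = 1.72e-07 and 0.00134), and the ribosomal protein list between MPP4 and each of the others (5.74e-07 for both). None of these passed with an estimated correlation (camera adjusted p = 0.96 for each).

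The other lineage and signalling lists did not pass. Camera adjusted p-values in LT-HSC, MPP3 and MPP4 were 0.819, 0.705 and 0.495 for erythroid genes, 0.175, 0.538 and 0.595 for granulocyte and monocyte genes, and 0.967, 0.495 and 0.939 for genes of stem cell identity. Interferon response genes had 0.697, 0.134 and 0.207, immediate early and stress genes 0.697, 0.773 and 0.723, NF-kB targets 0.175, 0.667 and 0.595, and Notch targets 0.403, 0.495 and 0.819. Among their members Mllt3 stood at log2 -0.56 ± 0.15 in LT-HSC (edgeR adjusted p = 0.222), Trim30a, an interferon-induced gene, at -0.51 ± 0.14 (edgeR adjusted p = 0.227) and Ccl3, an inflammatory chemokine, at 1.32 ± 0.39 (edgeR adjusted p = 0.258). Mllt3 and Trim30a passed as lower in the authors' deposited table. Adjusted over the list alone, 3 NF-kB targets passed as higher in LT-HSC (Ccl3, Relb and Tnf) and 2 erythroid genes passed in MPP4 in opposite directions (Epor higher and Hbb-bs lower), against 0 over all genes. Tnf in LT-HSC had 0, 29 and 14 reads in the KO libraries and 0 in each WT library. Relb and Hbb-bs are named after their values were seen. Median, mean and test differed in sign for the erythroid list in LT-HSC (median 0.08, mean -0.09) and MPP3 (median 0.003, mean -0.48, test upwards) and for stem cell identity in LT-HSC (median 0.09, test downwards). They also differed for immediate early genes in LT-HSC (median 0.05, mean -0.04) and MPP3 (median -0.006, test upwards) and for Notch targets in MPP3 (median 0.008, mean -0.27, test downwards).

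Genes of the sorting gates did not pass between genotypes as a list (camera adjusted p = 0.066, 0.495 and 0.259 in LT-HSC, MPP3 and MPP4), with Cd48 at log2 -0.83 and Flt3 at -0.36 in LT-HSC (edgeR adjusted p = 0.398 and 0.486). Of the markers of cells outside the gates, mature B and plasma cell genes had camera adjusted p-values of 0.723, 0.495 and 0.552, and T and NK cell genes 0.697, 0.469 and 0.738. Macrophage and dendritic cell genes had camera adjusted p-values of 0.495, 0.394 and 0.403, mast cell, basophil and eosinophil genes 0.482, 0.967 and 0.403, and stroma and endothelium genes 0.647, 0.595 and 0.738. The mature neutrophil list had 0.939 in MPP3 (median -0.18) and 0.259 in MPP4 (median -1.28, or -1.20 with members at 0 reads set to their bound). Mitochondrial transcripts had 0.469, 0.518 and 0.408. The only sex-linked gene tested, Xist, stood at log2 -0.19 in LT-HSC, 0.00 in MPP3 and 0.19 in MPP4. Adjusted over the list alone, Itgax and Pdgfrb passed in LT-HSC, Clec9a and Sdc1 in MPP3, and Prss34 and Sdc1 in MPP4. Some of these rest on few reads. Clec9a in MPP3 had 13, 12 and 8 reads in KO and 0 in each WT library. Prss34 in MPP4 had 22, 0 and 173 reads in WT and 0, 0 and 1 in KO. Median and mean differed in sign in MPP4 for mature B and plasma cell genes (-0.08 and 0.11) and for stroma and endothelium genes (0.07 and -0.23).

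Transcripts of other cell types varied between single libraries. The LT-HSC libraries WT 2 and WT 3 held 82.1 and 253 CPM of mature neutrophil transcripts while the other LT-HSC libraries held 3.64 to 9.21 CPM, and WT 3 also had more of the myeloid granule genes Mpo (129.85 CPM, against 5.59 to 8.48 CPM) and Elane (33.52 CPM). Of the 14 tested members of this list, 0 reached a mean of 5 CPM in every group and 0 stood in another list. In MPP3 the immunoglobulin light chain gene Igkc stood at 1235 CPM in WT 1, 1084 CPM in WT 2 and 1200 CPM in KO 1 and at 13.97 to 31.4 CPM in the other 3, and Jchain, which joins secreted antibodies, at 249.3, 243.47 and 151.05 CPM against 2.02 to 12.69 CPM. The mature B and plasma cell list summed to 1620, 1500 and 479 CPM in the MPP3 WT libraries and to 1660, 350 and 455 CPM in the KO libraries, and 7 of its 18 members had a mean of at least 5 CPM in every group. Without the LT-HSC libraries WT 2 and WT 3, the LT-HSC comparison gave 58 higher and 19 lower genes, of which 4 were among the 10 with all libraries. This sets the 3 KO libraries against WT 1 alone, with the spread taken from the other groups, so that these counts reflect a single WT library.

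**Figure D3:**
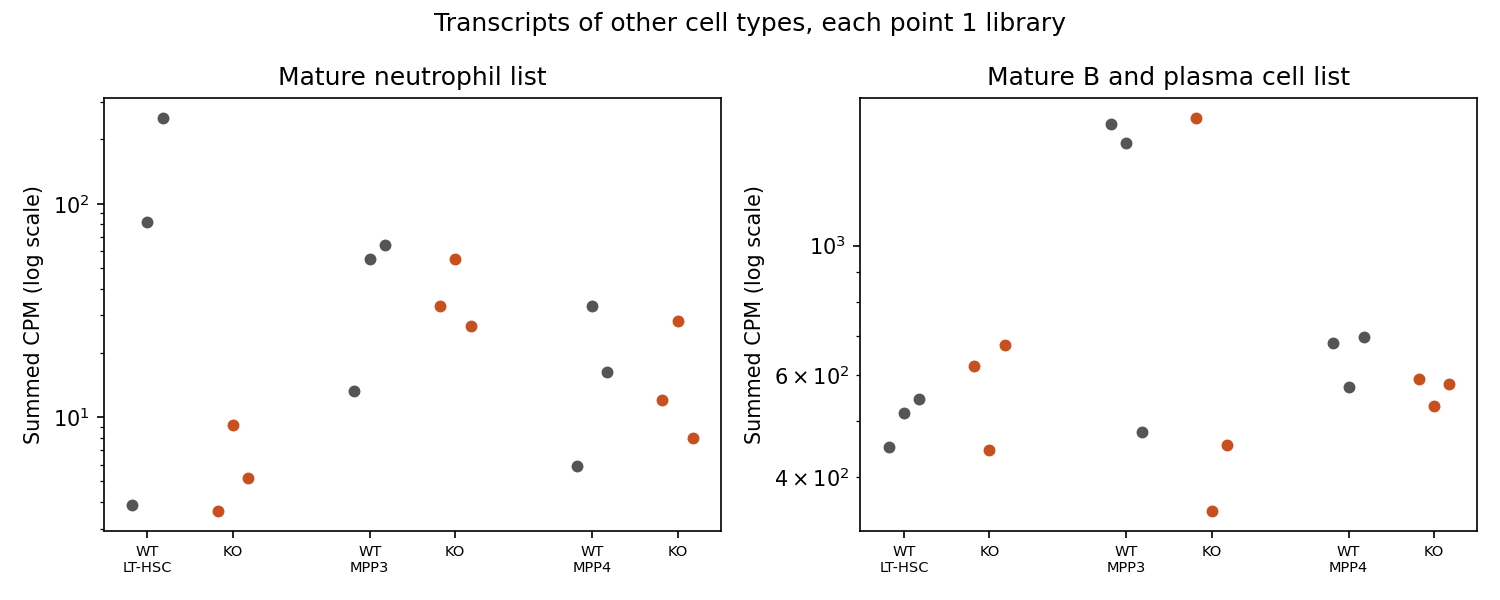
Summed CPM after TMM scaling of the mature neutrophil list and of the mature B and plasma cell list in each library (log axis), by population and genotype. The LT-HSC WT libraries 2 and 3 carry 82.1 and 253 CPM of neutrophil transcripts, and 3 MPP3 libraries carry 1500 to 1660 CPM of B and plasma cell transcripts.

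By edgeR genes within 20 Mb of Ikzf2 on chromosome 1 passed more often than genes elsewhere in LT-HSC. Within 20 Mb of Ikzf2 there were 252 tested genes other than Ikzf2. In LT-HSC 2 of these passed (Wdfy1 and Dock10) beside 7 outside (odds ratio 18.3, 95% interval 1.85 to 96.8, Fisher's exact p = 0.00796). In MPP3 1 passed (Wdfy1) beside 0 outside (Fisher's exact p = 0.0154), and in MPP4 1 (Wdfy1) beside 1 outside (odds ratio 63.9, 0.812 to 4780, Fisher's exact p = 0.0306). With 1 or 2 genes called these p-values reflect the position of Wdfy1 alone, the same gene in the same mice. Usp37, a deubiquitinase in this window, was at log2 0.77 in LT-HSC, 0.82 in MPP3 and 0.95 in MPP4, and passed in all 3 populations by DESeq2. By DESeq2 the window held 5 genes in LT-HSC (Creb1, Dock10, Stat4, Usp37 and Wdfy1, odds ratio 1.43, Fisher's exact p = 0.408). It held 4 in MPP3, Dock10, Usp37 and Wdfy1 among them (odds ratio 6.55, Fisher's exact p = 0.00443) and 3 in MPP4 (Dock10, Usp37 and Wdfy1, odds ratio 5.59, Fisher's exact p = 0.0199). Within 5 Mb there were 0, 0 and 0 genes by edgeR and 2 in LT-HSC (Creb1 and Usp37), 1 in MPP3 and 1 in MPP4 (Usp37 in both) by DESeq2 (Fisher's exact p = 0.182, 0.134 and 0.117). Within 50 Mb Fisher's exact p was 0.0271 in LT-HSC, 0.0294 in MPP3 and 0.0579 in MPP4 by edgeR, so that the call in MPP4 was lost, and 0.428, 0.0385 and 0.00464 by DESeq2. Selp, higher in MPP4 KO, lay elsewhere on chromosome 1. The frequency of passing genes on the rest of the chromosome, against genes beyond it, had a Fisher's exact p of 0.304 in LT-HSC, 1 in MPP3 and 0.0504 in MPP4 by edgeR. By DESeq2 it was 1, 0.722 and 0.0296, the last with 5 genes in MPP4 (Coq8a, Selp, Serpinb8, Stk25 and Tmem177, odds ratio 3.16). Of these all but Selp are named after their values were seen.

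**Figure D4:**
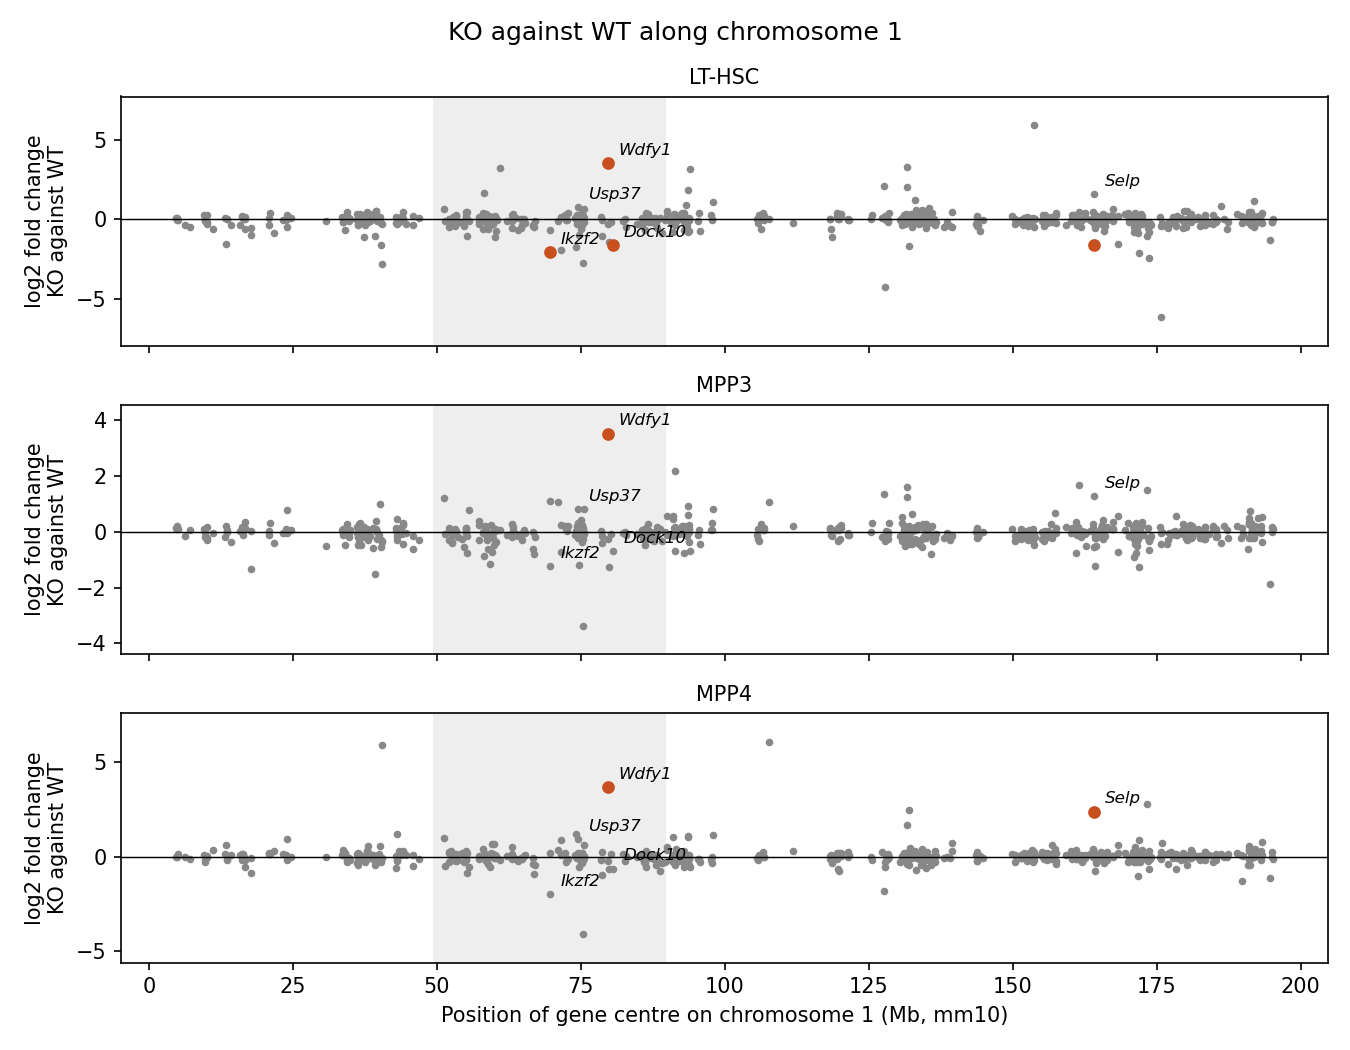
Log2 fold change of KO against WT for genes along chromosome 1 (x axis in Mb, mm10) with a mean of at least 5 CPM in some group, in each population (shading, 20 Mb either side of Ikzf2; orange, adjusted p under 0.05 by edgeR). Wdfy1 is at 3.55, 3.53 and 3.70 in LT-HSC, MPP3 and MPP4.

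By edgeR Wdfy1 was the 1 gene that passed in more than 1 population. Independent lists would share 0.000184 higher genes for LT-HSC with MPP3, 0.000368 for LT-HSC with MPP4 and 0.000123 for MPP3 with MPP4. By DESeq2 the shared higher genes numbered 12, 6 and 7 (0.147, 0.183 and 0.0297 from independent lists) and the shared lower genes 5, 2 and 3 (0.215, 0.12 and 0.0208). The 3 populations came from the same mice, so that the lists are not independent. In the authors' deposited table, 92 genes were higher and 110 lower in LT-HSC, 11 and 23 in MPP3 and 12 and 8 in MPP4, at the same adjusted p of 0.05. Of the genes that passed by edgeR, 9 of 10, 1 of 1 and 2 of 2 also passed in the authors' deposited table, as did 193, 31 and 20 of those that passed by DESeq2. Besides genes named above, Aldh1a1, Clu and Sdc1 in MPP3 and Ghr, Epor and Sdc1 in MPP4 passed in the authors' deposited table.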

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

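Of the tests in this part, the splits of the WT populations, the splits for the gene lists and the tests of neutrophil transcripts were chosen after the results were seen, and the splits for the counts between genotypes and of the differences between populations were set before. The interaction test of the difference itself picked out 4 values, all medians of a gene list. The mature neutrophil list had a KO effect that was higher by log2 4.28 in MPP3 than in LT-HSC and by 2.86 in MPP4 than in LT-HSC (camera adjusted p = 1.72e-07 and 0.00134). The ribosomal protein list had a KO effect of -0.38 in MPP4 relative to LT-HSC and of -0.29 in MPP4 relative to MPP3 (camera adjusted p = 5.74e-07 for both). With an estimated correlation the adjusted p was 0.96 for each of these 4 differences.

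The neutrophil difference rested on LT-HSC, where mature neutrophil transcripts were high in WT 2 and WT 3. The summed level in WT 1 was 3.86 CPM, within the 3.64 to 9.21 CPM of the KO libraries, so that mature neutrophil RNA in these 2 WT libraries is a candidate explanation, although the lineage-negative gate is meant to remove neutrophils. Loss of Helios as the cause would place all 3 WT libraries above all 3 KO libraries. This held for 2 of the 3, with WT 1 at the level of KO, and 1 library is too few to set loss of Helios aside. In the 7 genes lower in LT-HSC KO the WT 1 library, low in neutrophil transcripts, lay above all KO libraries in 7 of 7 (Dock10 at 374.58 against 103.27 to 127.07 CPM), and by DESeq2 in 119 of 130 lower genes (91.5%), although such genes were picked as lower in KO. Ikzf2 is the deleted gene. Of the other 6, 3 still passed without WT 2 and WT 3, which argues against neutrophil RNA as their whole cause, as far as the 1 WT library left can show. These were Dock10 (log2 -1.74 ± 0.16 against -1.62 ± 0.12 with all libraries), Ncf4 (-1.19 ± 0.23 against -1.09 ± 0.17) and the weakly expressed Itgax. The 3 others lost their calls, Arl11 with a smaller fold (-1.16 ± 0.26 against -1.69 ± 0.26) and Anxa6 with a larger error (-0.71 ± 0.18 against -0.74 ± 0.12). Anxa6 kept its fold, at 178.9, 197.02 and 177.85 CPM in WT 1, WT 2 and WT 3 against 97.54 to 124.01 CPM in KO. Its level did not follow the neutrophil transcripts, which argues against neutrophil RNA as its whole cause, as far as these libraries can show. For the others of the 3, neutrophil RNA and loss of Helios cannot be told apart. An earlier test of the 7 lower genes, by the order of their levels in the WT libraries, was replaced by the fit without WT 2 and WT 3. This was done after its result was seen, because chance gives most of its outcome.

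Other splits of the samples were too few, at 10 per comparison, for a share under 0.05. In LT-HSC 1 of 10 splits gave as many genes as the real 10, with 1 gene in the highest other; in MPP3 2 of 10 gave at least the real 1, with 9 in the highest other; and in MPP4 3 of 10 gave at least the real 2, with 6 in the highest other. The splits with 9 and with 6 genes both set WT 1, KO 1 and WT 2 against the rest, and call several times the real count, which points to a structure of the samples other than genotype; in MPP3 these are the libraries with plasma cell transcripts. For the differences between populations all 10 splits gave at least the real 0, with 4, 0 and 7 in the highest other for MPP3 against LT-HSC, MPP4 against LT-HSC and MPP4 against MPP3. For the WT populations 1 of 10 splits reached the real 2831, 4435 and 786 genes, with 0, 1 and 1 in the highest other. The camera p of the megakaryocyte and platelet list was reached by 1, 2 and 7 of 10 splits in LT-HSC, MPP3 and MPP4 (real 0.000497, 3.03e-06 and 0.129; smallest other 0.00123, 9.44e-13 and 3.48e-10), and that of the lymphoid priming list by 1, 1 and 5 (real 0.00462, 2.72e-07 and 0.0101; smallest other 0.0157, 0.000472 and 4.95e-06). The smallest other p of the megakaryocyte list in MPP3 and MPP4 lay far below the real one, which again points to a structure of the samples. For both lists and in each population the smallest other p was under 0.05. A camera p of this size at the preset correlation therefore does not by itself mark the genotype.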

How the results depend on the processing

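The robust estimation, the term for the libraries numbered 1, the libraries numbered 2 and 3 alone, the runs without libraries carrying neutrophil or plasma cell transcripts or without immunoglobulin genes, and the DESeq2 and authors' calls near Ikzf2 are tests that were chosen after the results were seen. Higher and lower genes in LT-HSC KO numbered 111 and 130 by DESeq2, 7 and 12 with the libraries numbered 2 and 3, and 58 and 19 without WT 2 and WT 3, which leaves 1 WT library. By limma voom 25 were higher, and 12 were lower with no filter and 2 in the fit to LT-HSC alone. With 1 library left out they ran from 1 to 5 and from 1 to 9. In MPP3 they numbered 20 and 25 by DESeq2 and 0 and 1 without the libraries with plasma cell transcripts, again with 1 WT library; 4 were higher with numbers 2 and 3, and 1 was lower with no filter, by limma voom, and at most (0 to 1) with 1 library left out. In MPP4 they numbered 25 and 14 by DESeq2, 6 and 1 with no filter and 1 and 2 by limma voom; 1 was higher in the fit to MPP4 alone, 7 with numbers 2 and 3, and 1 to 5 with 1 library left out. Differences between populations numbered 4, 49 and 8 by DESeq2, 0 to 2 between MPP4 and either other population with 1 mouse left out. In WT the counts were 1201, 2174 and 482 with a log2 fold change of at least 1, 1230 by DESeq2 between MPP4 and MPP3, and 1296 to 3212, 2613 to 4756 and 366 to 893 with 1 mouse left out. The counts with a minimum log2 fold change are lower by construction; for the other changes the cause was not tested.

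The replicate block on the number shared by a WT and a KO library gave 7 higher and 13 lower genes in LT-HSC, and the mouse as a fixed block in edgeR gave 1 gene for the difference between MPP4 and LT-HSC; the block also left the lymphoid priming list in MPP4 at a median of -0.13 without its call (camera adjusted p = 0.0506) and Selp in MPP4 no longer past the threshold. Correlations of WT and KO libraries of the same number and population were 0.035 to 0.147, with 3 of 9 over 0.1, against -0.24 to 0.067 for different numbers, and 16 of 18 libraries correlated best with their own number in the other genotype, a hint from the data and not the design. Blocking on the mouse changed no call of the list differences between populations.

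With an estimated correlation or by fry, which change the test and not the fold changes, the lists had no call: megakaryocyte and platelet 0.25 in LT-HSC and 0.38 in MPP3, lymphoid priming -0.13, -0.24 and -0.12 in LT-HSC, MPP3 and MPP4. Calls also ended for both lists in LT-HSC without WT 2 and WT 3 (0.24 and 0.048), for lymphoid priming in MPP3 without the libraries with plasma cell transcripts (-0.10), and for lymphoid priming in MPP4 with no filter (-0.12), a term for number 1 (-0.13) or numbers 2 and 3 (-0.034), where megakaryocyte and platelet genes passed (0.062). With 1 library left out the megakaryocyte and platelet medians ran from 0.18 to 0.41 in LT-HSC, from 0.211 to 0.539 in MPP3 and from -0.092 to 0.15 in MPP4, and the lymphoid priming medians from -0.09 to -0.022 in LT-HSC, from -0.364 to -0.231 in MPP3 and from -0.20 to 0.010 in MPP4. The highest, without MPP4 WT 1, turned the sign. Against the 1 WT library left without the LT-HSC libraries WT 2 and WT 3, the direction of the median or of the test also turned for granulocyte and monocyte genes (0.46), immediate early genes (-0.44) and mature neutrophil genes (3.30), and, also with 1 WT library, without the libraries with plasma cell transcripts for cell cycle (0.019) and ribosomal protein genes (-0.086) in MPP3. Within 5 Mb of Ikzf2 0 genes passed by edgeR in LT-HSC, MPP3 and MPP4, and 2, 1 and 1 by DESeq2 and in the authors' deposited table. Within 20 Mb 2, 1 and 1 passed by edgeR, and 5, 4 and 3 by DESeq2 and in that table. The cause was not tested. Of the values of named genes under the alternatives, 1918 stayed on their side of the threshold, 37 gained and 76 lost it. Most that stayed belonged to genes that had not passed, and all 76 losses fell on genes that had. In LT-HSC the losses ran from 0 of 16 alternatives for Wdfy1 and Dock10 to 12 of 16 for Nlrp6, with 11 of 16 for Tuba1c and 9 of 16 for Anxa6. Of the other lists 387 stayed, 19 gained, 26 lost and 5 turned direction, and all 12 list sums stayed. With 21053050 to 45410959 counts per library and 3 mice per group, edgeR recovered 65% of the genes simulated with a log2 fold change of 1 in MPP3. In that simulation 172 genes passed, against 1 in the real MPP3 comparison, so that the share may be lower in the real data.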

Other observations

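Of the tests in this part, those of the Rplp0 copies and of the Gene Ontology terms were chosen after the results were seen, and the test of genes near Ikzf2 was set before. Among 1145 Gene Ontology terms 20 were higher and 4 lower in LT-HSC KO, 8 and 11 in MPP3 KO and 2 and 4 in MPP4 KO by camera, and 0 passed with an estimated correlation. In LT-HSC KO genes of ubiquitin-independent proteasomal degradation were higher (median log2 0.32, camera adjusted p = 6.98e-07), as were those of the electron transport chain (0.24, adjusted p = 0.000517) and of steroid biosynthesis (0.37, adjusted p = 0.000517), and neutrophil chemotaxis genes were lower (-0.36, adjusted p = 0.00162), the last in the population whose WT 2 and WT 3 libraries held mature neutrophil transcripts. In MPP3 KO electron transport chain genes were higher (camera adjusted p = 0.00441) and B cell receptor signalling genes lower (-0.72, adjusted p = 0.000195), the latter in the population whose WT 1, WT 2 and KO 1 libraries held plasma cell transcripts. In MPP4 KO genes of classical complement activation were lower (camera adjusted p = 0.00448). So were those of positive regulation of B cell activation (-0.925, adjusted p = 0.0211) and B cell receptor signalling (-0.332, adjusted p = 0.0315). In MPP3 the complement and B cell receptor terms had the same median (-0.72), so that these terms may rest on shared genes. This was not tested.

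Wdfy1 and Dock10 lie within 20 Mb of Ikzf2, and by edgeR genes in this window passed more often than others in LT-HSC (Fisher's exact p = 0.00796, against 0.0154 in MPP3 and 0.0306 in MPP4, which rest on Wdfy1 alone). By DESeq2 they did so in MPP3 and MPP4 (0.00443 and 0.0199) but not in LT-HSC (0.408), and in MPP4 genes on the rest of chromosome 1 did so too (0.0296). Sequence of another strain flanking the targeted allele is a candidate explanation. With so few genes passing, the edgeR tests could show an excess near Ikzf2 but could not argue against this explanation. Within 5 Mb, where 0 genes passed by edgeR, the interval of the odds ratio still reached 163 in LT-HSC, 10200 in MPP3 and 1700 in MPP4. An effect of the loss of Ikzf2 on its neighbours stays open, since every KO mouse carries the allele. Selp lies outside the window.

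A group of processed pseudogenes set KO mice 2 and 3 apart in all 3 populations, with 6 genes over 4 times above every other library. Among them was Gm8730, at 50.65, 75.74 and 64.03 CPM in mouse 2 and 32.58, 40.9 and 29.51 CPM in mouse 3 in LT-HSC, MPP3 and MPP4. No other single mouse or pair of mice had more than 2 such genes. Those, named after their values were seen, included Ctse, at 395.97 to 438.19 CPM in KO mouse 2 against 30.82 to 70.8 CPM elsewhere. They also included Gm6768, low in KO mouse 2 and WT mouse 3, across the genotypes (4.32 to 6.62 CPM against 36.69 to 51.29 CPM). Loss of Helios is argued against by KO mouse 1, where Gm8730 reached at most 0.41 CPM, and a batch of the libraries numbered 2 and 3 by their WT libraries, where it reached at most 0.63 CPM. Of the 6 genes 5 had a sequence, and all 5 aligned to Rplp0, a ribosomal stalk protein gene, with 86.1% to 98.7% identity; Rplp0 itself was lowest in KO mouse 2 in 3 of 3 populations (186.32, 289.33 and 232.98 CPM against 360.49 to 721.67 CPM). In KO mouse 3 it was 428.07, 515.13 and 365.55 CPM, within the WT range in LT-HSC and MPP3 and below it in MPP4. Reads of a variant Rplp0 assigned to its copies may account for these genes in mouse 2, and in mouse 3 this stays open. These copies are among the genes that DESeq2 shares between populations.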
